A study of Mus musculus with 13 samples.

How the data were processed

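A total of 13 libraries of mouse heart RNA were analysed from the deposited tables of values per gene; the sequencing reads were not used here. Per the labels, whole hearts of C57BL/6 mice were flash frozen, RNA was taken with Trizol, and libraries were made with the TruSeq RNA kit. The first experiment holds 5 libraries, 1 per week from 0 to 4 of doxorubicin injection, each from 5 hearts mixed before extraction. The second holds 8: WT_CONTROL (1), WT_DCM (3), KO_CONTROL (1) and KO_DCM (3). Per the submitters' processing notes, STAR 2.6.1b, R 3.5.1 and the mm10 genome were used. The counting program, the gene annotation and whether counting used strand are not given in the sources used here.

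The first experiment's files hold a count and a TPM for each of 31017 gene symbols, per the file headers. The deposited counts are estimated or mean counts, since 6 to 11 genes per library hold values that are not whole; these were rounded. The deposited TPM sum to between 999399 and 999548 per library and were used only to check the unit. The second experiment's files hold an expected count, a TPM and an FPKM for each of 47069 Ensembl genes, per the file headers; 46488 of these had a symbol in the annotation table. The authors' expected counts are whole numbers with no normalization across libraries. The authors' FPKM are scaled to the library's summed expected count and the gene's effective length, per the file headers and the values, and served 1 alternative test. The authors' TPM of the second experiment, as named in the file headers, were not used.

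Total counts ran from 13855920 to 15834666 in the first experiment and from 20656861 to 26006978 in the second. Mitochondrial genes took 24.3% to 28.9% of counts. At this depth a gene with 110 counts against 32, such as Msr1 at weeks 0 and 4, has a ratio with a 95% counting interval from 0.208 to 0.476. Such intervals cover counting error only, not the spread between animals. The gene mt-Co3 had 861 to 1285 counts per library in the first experiment and 422669 to 520390 in the second, and its nuclear copy Gm28437 in the second had 0.998 to 1.005 times its counts. Reads shared by such copies cannot be assigned to either entry, and levels were not compared across experiments, only fold changes.

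For the second experiment, counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter by group (16050 genes kept), 1 model with a mean per group over all 8 libraries, and the quasi-likelihood F test without robust estimation. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. TMM factors ran from 0.911 to 1.082, and the common biological coefficient of variation was 0.177. A lone control library adds no spread of its own and is assumed to vary like the DCM groups. CPM are scaled by TMM. Means are given with SD, and log2 fold changes with SE.

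The 39 gene lists were written before the data were examined, as were the design, the rule for named genes and the alternatives not called later below. Of these lists, 38 had at least 3 measured genes and were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and again with the correlation estimated. Adjusted p of lists are Benjamini-Hochberg values over the 38 lists of a comparison. Where the estimated correlation of a list lies well above 0.01, its p with the preset correlation overstates the evidence. List members were also adjusted over the list alone. A list score is the mean log2 CPM of its members in a library, around the mean over libraries.

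The first experiment has 1 library per week and was not tested. Log2 fold changes against week 0 use TMM scaling and a prior of 0.5 CPM, for 13323 genes with at least 1 CPM in at least 1 library. The median of each list was set against 10000 random lists of its size, drawn from 20 bins of mean expression, and its percentile describes these libraries only. Genes of the random lists were drawn independently, so the percentiles do not allow for co-expression within a list and are no test of it. The difference between the 2 control libraries was taken in the same way. Fold changes of genes at 0 counts depend on the prior, so bounds were computed against a floor of 3 counts over the group. The experiments were compared by correlation across 12885 genes.

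Named genes followed a rule: up to 10 genes in each direction past the threshold (5 for the interaction), with at least 1 CPM in a group, no overlap between groups and no predicted-gene name. For the time course it was the 10 largest changes each way at week 4, with at least 5 CPM. Msr1, Myc and up to 4 genes per list with the smallest p, or with the largest change at week 4, were added. Where fewer genes passed, none took their place: 8, 0, 8 and 4 genes past the threshold met the rule in the 4 tested comparisons, of which 1 gene is not reported here. Gm43302 was named outside this rule, after its values were seen.

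The methods were tested on simulated counts with 200 genes changed, 100 per fold size. The changed genes had a mean of at least 1 CPM, and each gene varied independently around 1 common mean. The simulated libraries held no gene-length class or tissue differences, so the shares below do not cover such structure in the real libraries. For KO_DCM against WT_DCM (15708 genes), 77% of genes changed 2-fold and 99% of those changed 4-fold were recovered, with 187 calls of which 11 were wrong. For WT_DCM against WT_CONTROL (15722 genes) these shares were 42% and 94%, with 142 calls and 6 wrong. For KO_DCM against KO_CONTROL (15710 genes) they were 36% and 94%, with 137 calls and 7 wrong. With genes drawn independently, camera found the 1 raised list of 38 and called 0 others, which does not test it on correlated genes. In the simulated time course of 37 lists the raised list lay at percentile 100, and 4 others lay outside the central 95%.

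The alternatives were RLE and upper-quartile scaling, no filter and a filter at a mean of 1 CPM, the 6 DCM libraries alone, a replicate block, leaving out each DCM library, robust estimation, an added 2-fold threshold, DESeq2 1.42.0, limma-voom and limma-trend on log2 of FPKM plus 1. For the time course they were a prior of 2 CPM, total-count scaling and floors of 5 and 0.1 CPM. Further alternatives were chosen after seeing the data: a batch term for gene-length class, the atrial score as a covariate, leaving out mitochondrial genes and their nuclear copies, leaving out KO_CONTROL, and fits of DCM and control of 1 label alone (4 libraries). The gene-length class splits libraries at 1.1 on the ratio of summed FPKM to the fixed total to which TPM are scaled. This ratio rises with the share of counts in short genes. That ratio was 1.08 in WT_CONTROL, 1.17, 1.08 and 1.09 in WT_DCM, 1.18 in KO_CONTROL and 1.19, 1.08 and 1.14 in KO_DCM, and principal component 1, with 30.4% of the variance, follows the class. The labels give no batch, so the class comes from the data alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.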

Results

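The series measured RNA from mouse hearts by sequencing, in 13 libraries that form 2 experiments on the C57BL/6 strain. In the first experiment, wild-type mice at postnatal week 12 received injections of doxorubicin, an anthracycline cancer drug that damages heart muscle, for 0, 1, 2, 3 or 4 weeks. The RNA of 5 hearts was mixed before extraction at each time, which gave 1 library per week. Total counts per library ranged from 13855920 to 15834666. In the second experiment, hearts came from mice at postnatal week 8, either wild type (WT) or labelled as lacking SR-A1 (KO). SR-A1 is a scavenger receptor of macrophages that binds modified lipoproteins and is encoded by Msr1. The groups were WT_CONTROL (1 library), WT_DCM (3 libraries), KO_CONTROL (1 library) and KO_DCM (3 libraries), with total counts of 20656861 to 26006978. The labels do not expand DCM and give no drug or duration for these mice; the series title names doxorubicin cardiomyopathy. They do not say that replicates came from separate animals. Counts of same-group libraries differed by 11.13 to 58.16 in chi-square per degree of freedom, where counting noise alone gives about 1, and expression of atrial genes differed within both DCM groups (below), which repeats of 1 RNA sample would not give. The p-values measure the spread between these libraries. With 1 library, WT_CONTROL, KO_CONTROL and each week have no replicate error.

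Msr1, the gene named by the knockout label, was read in libraries of both genotypes, at a similar level in the DCM groups. Its counts were 53 in WT_CONTROL, 87, 100 and 70 in WT_DCM, 83 in KO_CONTROL and 72, 77 and 99 in KO_DCM. Msr1 was at 1.94 CPM (counts scaled to library size) in WT_CONTROL and 4.03 CPM in KO_CONTROL, with 1 library each. Mean Msr1 expression was 3.85 ± 0.729 CPM (SD, n = 3) in WT_DCM and 3.73 ± 0.873 CPM (SD, n = 3) in KO_DCM. The log2 fold change was -0.05 ± 0.235 (SE), with an adjusted p of 0.99 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out WT_DCM replicate 1, WT_DCM replicate 2 or KO_DCM replicate 2 turned its sign, to 0.02, 0.05 and 0.11. The labels do not say which part of Msr1 was deleted, and a count over the whole gene does not test a part of it. The genotype names below are therefore those of the labels, and every direction between KO and WT rests on them. Myc, the growth-promoting transcription factor c-Myc named in the series title, had counts of 74 in WT_CONTROL, 42, 38 and 43 in WT_DCM, 90 in KO_CONTROL and 64, 39 and 135 in KO_DCM. Its log2 fold change between KO_DCM and WT_DCM was 0.98 ± 0.448 (SE), with an adjusted p of 0.772 by the same test, and the 3 KO_DCM values spread over those of WT_DCM. The c-Myc target list had a median log2 fold change of 0.10 over 30 genes in that comparison, with 0 of them past the threshold over all genes or adjusted over the list alone, and did not pass camera's test of gene lists (adjusted p = 0.0689).

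The comparison of KO_DCM with WT_DCM asks how diseased hearts labelled as lacking SR-A1 differ from wild-type ones. Interferon-induced genes were higher in the libraries labelled KO_DCM. Gbp6, an interferon-induced guanylate-binding protein of cell-autonomous defence, rose from 37.1 ± 1.34 CPM (SD, n = 3) in WT_DCM to 89.9 ± 3.51 CPM (SD, n = 3) in KO_DCM. It lay at 15.9 CPM in WT_CONTROL and 29.9 CPM in KO_CONTROL. Irf7, a master regulator of type I interferon production, rose from 15.3 ± 3.13 CPM to 86.6 ± 39.6 CPM (SD, n = 3 each). Its level was 25.85 CPM in WT_CONTROL, above that of WT_DCM, and 10.93 CPM in KO_CONTROL. The gene that fell was Fos, an immediate-early transcription factor, from 28.3 ± 5.26 CPM to 8.67 ± 0.792 CPM (SD, n = 3 each), against 8.32 CPM in WT_CONTROL and 8.02 CPM in KO_CONTROL.

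By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were 1.28 ± 0.107 (SE) for Gbp6 at an adjusted p of 0.00524, 2.5 ± 0.303 for Irf7 at 0.026 and -1.70 ± 0.162 for Fos at 0.00738. In the same test Gbp10, another guanylate-binding protein, had a log2 fold change of 1.87 ± 0.182 (SE, adjusted p = 0.00738). Bst2, which tethers budding virus to the cell surface, had 1.26 ± 0.116 (SE, adjusted p = 0.00738). Gbp3 and Lgals3bp, a secreted glycoprotein that binds galectin-3, had 1.19 ± 0.136 and 1.40 ± 0.158 (SE), each at an adjusted p of 0.0191. The predicted gene Gm43302 also passed, at 1.34 ± 0.11 (SE, adjusted p = 0.00524); it falls outside the rule for named genes and was chosen after its values were seen. On chromosome 5 of GRCm38, Gm43302 spans bases 105214907 to 105293695, over Gbp10 at 105215699 to 105239533 and nearly all of Gbp6 at 105270702 to 105293698. Reads of these 3 genes can therefore be shared, and their values are uncertain as separate measurements. Irf7 lies on chromosome 7 at 141262706 to 141266481 and Fos on chromosome 12 at 85473890 to 85477273. Leaving out WT_DCM replicate 2 ended the call of each of these genes at log2 fold changes from -1.56 for Fos to 2.63 for Irf7. Calls were also lost for Gbp3, Lgals3bp and Irf7 without WT_DCM replicate 1 (1.1, 1.38 and 2.35) and without WT_DCM replicate 3 (1.20, 1.41 and 2.54), and for Bst2 and Gbp10 without WT_DCM replicate 3 (1.19 and 1.81).

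**Figure D1:**
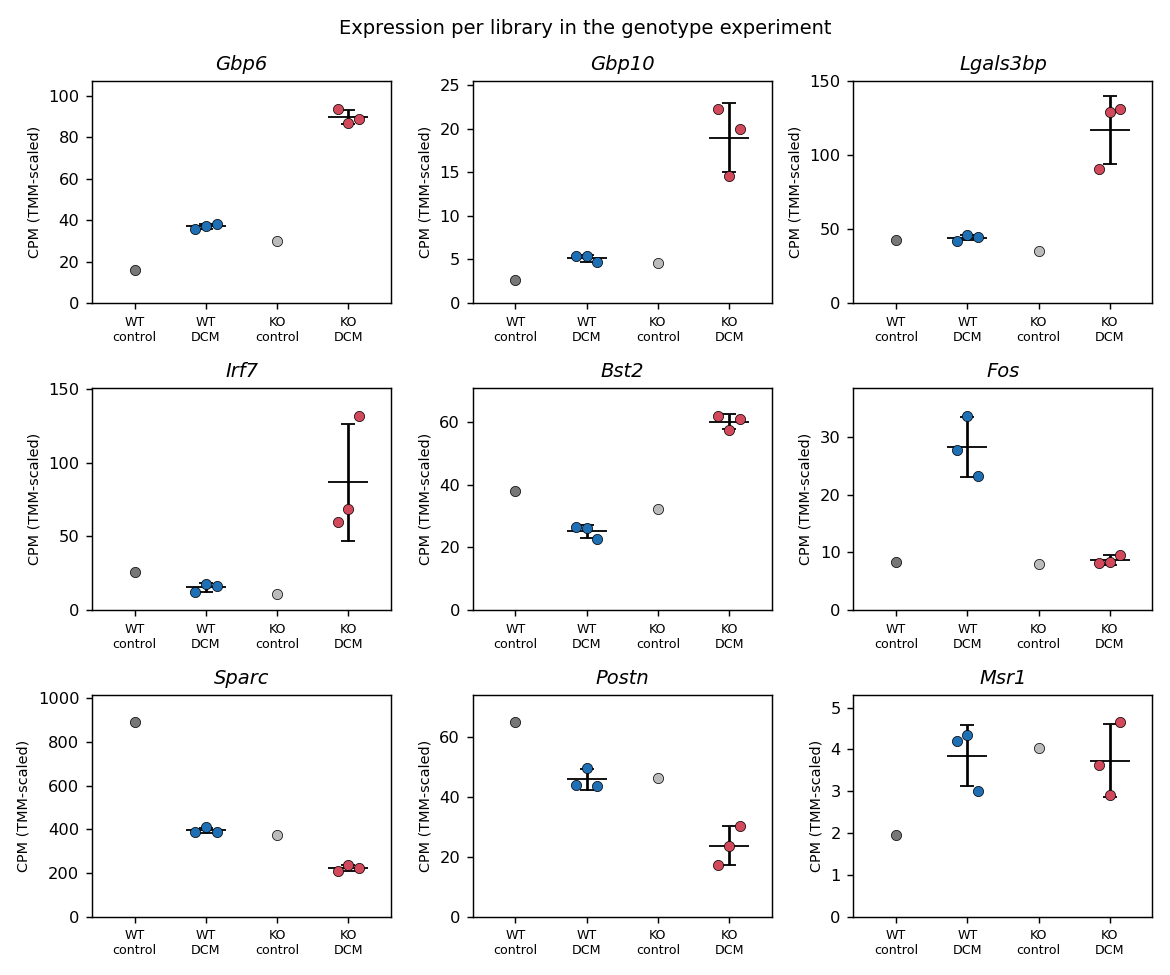
Expression of 9 genes in each of the 8 libraries of the second experiment, in CPM scaled by TMM (y axis), by group (x axis); points are libraries, and bars are the mean ± SD of the groups of 3. The 3 KO_DCM points of Gbp6, Gbp10, Lgals3bp, Irf7 and Bst2 lie above the WT_DCM points, those of Fos, Sparc and Postn lie below them, and those of Msr1 overlap with them.

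All 26 measured genes of the interferon list had a positive log2 fold change in KO_DCM against WT_DCM, with a median of 1.15. Of these, 24 rose when adjusted over the list alone and 3 rose when adjusted over all genes, Irf7 and Gbp3 among them. Xaf1, an interferon-induced promoter of cell death, had a log2 fold change of 1.24 ± 0.197 (SE) and an adjusted p of 0.0967 over all genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without KO_DCM replicate 1 Xaf1 passed over all genes, at a log2 fold change of 1.44. By camera the list had an adjusted p of 3.03e-62 with the preset correlation, and an adjusted p of 0.154 with an estimated correlation. The interferon score was -0.009 in WT_CONTROL and -0.751 in KO_CONTROL. It was -0.526, -0.256 and -0.426 in WT_DCM, and 0.151, 0.92 and 0.896 in KO_DCM. WT_DCM thus lay below WT_CONTROL and KO_DCM above it, so part of the difference is a low WT_DCM level. The 8 libraries also fell into 2 classes by the share of counts in short genes, described with the processing. The median difference of the interferon list was 1.24 between the 1 KO_DCM and 2 WT_DCM libraries of the low class, and 0.96 between the 2 KO_DCM and 1 WT_DCM libraries of the high class.

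Extracellular matrix genes were lower in the libraries labelled KO_DCM, with a list median of -0.48 over 35 genes. Adjusted over the list alone 8 of them fell, and 0 passed over all genes. Sparc, a collagen-binding matrix protein, averaged 225 ± 14.1 CPM in KO_DCM and 396 ± 12.7 CPM in WT_DCM (SD, n = 3 each), against 890 CPM in WT_CONTROL and 374 CPM in KO_CONTROL. Its log2 fold change was -0.82 ± 0.117 (SE), and that of Postn, a matrix protein of activated fibroblasts, was -0.95 ± 0.191 (SE). Both missed the threshold over all genes, at adjusted p of 0.0715 and 0.233 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without KO_DCM replicate 2 Sparc passed, at a log2 fold change of -0.86. The matrix list had a camera adjusted p of 9.83e-19 with the preset correlation, and an adjusted p of 0.35 with an estimated correlation. Within the low and high classes of libraries its median difference was -0.44 and -0.54. The matrix score was -0.713, -0.382 and -0.007 in KO_DCM and 0.105, 0.325 and -0.077 in WT_DCM, so the groups overlapped. In the same order of libraries the atrial score (below) was -1.31, -2.44 and 1.66, and 1.51, 0.08 and -0.67. The adipocyte score was -0.784, -0.86 and -0.189, and 0.376, 0.365 and -0.28. The matrix difference therefore comes with differences in markers of other tissue. The fibroblast list had a median of -0.21 over 14 genes, with 1 that fell adjusted over the list alone (Mfap4, log2 fold change -1.48 ± 0.366, SE) and 0 over all genes. Its adjusted p was 2.62e-04 with the preset and 0.395 with an estimated correlation, and its median was -0.33 without WT_DCM replicate 3 and -0.34 without KO_DCM replicate 3.

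Cell-cycle genes had a median log2 fold change of -0.61 over 38 genes, with 0 past the threshold over all genes or adjusted over the list alone. Among them Prc1, a spindle midzone protein of cell division, averaged 0.678 ± 0.169 CPM in KO_DCM and 1.51 ± 0.348 CPM in WT_DCM (SD, n = 3 each), so these changes concern low counts. The cell-cycle list had a camera adjusted p of 1.09e-08 with the preset correlation and of 0.184 with an estimated correlation, and class differences of -0.29 and -0.33; without WT_DCM replicate 2 its median was -0.41. Adipocyte genes had a median of -1.06 over 12 genes; 4 fell adjusted over the list alone and 0 over all genes. Plin1, which coats the lipid droplets of fat cells, averaged 0.223 ± 0.0936 CPM in KO_DCM and 1.47 ± 1.02 CPM in WT_DCM (SD, n = 3 each). The adipocyte list had an adjusted p of 8.51e-08 with the preset and 0.274 with an estimated correlation, and class differences of -0.77 and -0.69; without KO_DCM replicate 3 its median was -1.7.

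The 3 macrophage lists and those of neutrophils, T and NK cells and B and plasma cells had positive medians in KO_DCM against WT_DCM, with few or 0 members past a threshold, while the mast-cell list had a negative one. The pan-macrophage list had a median of 0.51 over 18 genes, with 2 that rose adjusted over the list alone and 0 over all genes. Those were Mpeg1, a pore-forming protein of phagocytes, at a log2 fold change of 0.94 ± 0.217 (SE), and Fcgr1, a high-affinity antibody receptor, at 1.04 ± 0.245 (SE). The list had a camera adjusted p of 1.85e-10 with the preset correlation and of 0.35 with an estimated correlation, and class differences of 0.17 and 0.40; without KO_DCM replicate 3 its median was 0.26. The resident (reparative) cardiac macrophage list had a median of 0.27 over 22 genes, with 0 past the threshold over all genes or adjusted over the list alone. Timd4, a receptor for dying cells on resident macrophages, had a log2 fold change of 0.75 ± 0.228 (SE) without passing. This list had an adjusted p of 1.89e-04 with the preset and 0.495 with an estimated correlation; without KO_DCM replicate 3 its median was 0.06 and the call was lost. The monocyte-derived macrophage list had a median of 0.69 over 15 genes, with 2 that rose adjusted over the list alone (Plac8 and Ms4a4c) and 0 over all genes. Its adjusted p was 0.00185 with the preset and 0.35 with an estimated correlation, and without KO_DCM replicate 3 the call was lost at a median of 0.41, and without WT_DCM replicate 3 the median was 0.39. Class II antigen-presentation genes had a median of 0.68, positive in 10 of 10 genes, at an adjusted p of 2.85e-07 with the preset and 0.311 with an estimated correlation; without WT_DCM replicate 3 the median was 0.43. None of these 10 passed over all genes or adjusted over the list alone. The monocyte-attracting chemokines Ccl8 and Ccl12 had log2 fold changes of 3.15 ± 0.649 and 2.28 ± 0.494 (SE). They were the 2 of 16 measured inflammatory cytokine genes that rose adjusted over the list alone, with 0 over all genes; without KO_DCM replicate 2 both passed over all genes, at 3.54 and 2.62. That list had a median of 0.18 and an adjusted p of 0.00254 with the preset and 0.35 with an estimated correlation; its call was lost without WT_DCM replicate 3 (median 0.13) or KO_DCM replicate 3 (median 0.22), and its median was 0.675 and 0.35 without WT_DCM replicates 1 and 2 and 0.35 and 0.50 without KO_DCM replicates 1 and 2. The neutrophil list had a median of 1.22, positive in 6 of 6 genes, at an adjusted p of 2.12e-04 with the preset and 0.35 with an estimated correlation, and class differences of 0.29 and 0.50; without KO_DCM replicate 3 its median was 0.76. The T and NK cell list had a median of 0.62 over 13 genes and the B and plasma cell list one of 0.48 over 14, at adjusted p of 0.00279 and 0.0185 with the preset and 0.424 and 0.515 with an estimated correlation. In these 3 lists 0 genes passed over all genes or adjusted over the list alone. The T and NK cell call was lost without WT_DCM replicate 3 (median 0.41) or KO_DCM replicate 3 (median 0.38), with medians of 1.12 and 0.94 without WT_DCM replicate 1 and KO_DCM replicate 2, and the B and plasma cell call without WT_DCM replicate 3 (median 0.33) or KO_DCM replicate 1 (median 0.095). The mast-cell list had a median of -0.41, positive in 0 of 5 genes, of which 0 passed over all genes or adjusted over the list alone. That list had an adjusted p of 0.0273 with the preset and 0.35 with an estimated correlation, and the call was lost without WT_DCM replicate 1 (median -0.34), KO_DCM replicate 2 (median -0.52) or KO_DCM replicate 3 (median -0.20); without WT_DCM replicate 2 and KO_DCM replicate 1 the median was -0.63 and -0.85. Positive medians were therefore not particular to the macrophage lists.

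Genes of the stressed heart varied among the KO_DCM libraries. Myh7, the fetal myosin heavy chain that is re-expressed in stressed ventricles, averaged 2256 ± 1781 CPM in KO_DCM and 640 ± 13.7 CPM in WT_DCM (SD, n = 3 each). Gdf15, a stress-induced cytokine, averaged 21.9 ± 32.6 CPM and 1.29 ± 0.329 CPM, while Acta1, skeletal actin, averaged 191 ± 21.6 CPM and 491 ± 195 CPM (SD, n = 3 each). The cardiac stress list had a median of 0.65 over 17 genes, with 3 higher and 1 lower adjusted over the list alone and 0 over all genes. Its adjusted p was 0.00255 with the preset and 0.4 with an estimated correlation. The call was lost without WT_DCM replicate 2 (median 0.50) or KO_DCM replicate 3 (median 0.11), and the class differences were 0.02 and 0.37. Myh7 passed over all genes without KO_DCM replicate 2, at a log2 fold change of 2.24. Heat-shock genes had a median of -0.15 and a mean of -0.69 over 13 genes, with 4 that fell adjusted over the list alone and 0 over all genes. The mean rests on Hspa1a and Hspa1b, near-identical inducible chaperones whose reads cannot be fully told apart, which averaged 54.3 ± 67.1 and 53.2 ± 65.2 CPM in WT_DCM (SD, n = 3). The heat-shock list had an adjusted p of 0.00662 with the preset and 0.4 with an estimated correlation; its call was lost without WT_DCM replicate 3 (median -0.16) or KO_DCM replicate 2 (median -0.15), its median was -0.23 without WT_DCM replicate 1, and the class differences were -0.22 and 0.07. Ribosomal protein genes were higher in 45 of 45 cases with a median of 0.37, at an adjusted p of 2.45e-18 with the preset and 0.4 with an estimated correlation, with 0 past the threshold over all genes or adjusted over the list alone. Their class differences were 0.11 and 0.30, their median was 0.24 without KO_DCM replicate 3, and their level moved with the gene-length class. That class was drawn from the same counts, by the share in short genes, so the match is no separate evidence of a technical cause.

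Of the other lists that passed camera with the preset correlation in KO_DCM against WT_DCM, the immediate-early list had a median of -0.25 over 22 genes, of which Fos alone fell adjusted over the list alone or over all genes. Camera gave this list an adjusted p of 8.44e-04 with the preset and 0.248 with an estimated correlation, and its class differences were -0.31 and -0.11. The call was lost without KO_DCM replicate 2 (median -0.22), and the median was -0.11 without WT_DCM replicate 1. The oxidative stress (NRF2) list had a median of 0.285 over 27 genes, with 2 that rose adjusted over the list alone (Gsta1 and Ncf1), and the alternative (M2) activation list one of 0.33 over 13; both calls were lost without KO_DCM replicate 3 (medians 0.045 and 0.145). Gsta1 passed over all genes without KO_DCM replicate 2. The unfolded protein response list, at 0.325 over 24 genes, lost its call without WT_DCM replicate 3 (0.20), KO_DCM replicate 1 (0.041) or KO_DCM replicate 3 (0.22), and had 0.56 without KO_DCM replicate 2. The glucocorticoid-response list, at 0.27 over 16 genes, lost it without WT_DCM replicate 1 (0.20), WT_DCM replicate 2 (0.19) or KO_DCM replicate 3 (0.022), and had 0.475, 0.46 and 0.48 without WT_DCM replicate 3, KO_DCM replicate 1 and KO_DCM replicate 2. The muscle atrophy list (0.099 over 24 genes) lost it without WT_DCM replicates 1 and 2 (0.076 and 0.058) or KO_DCM replicates 1 and 3 (0.10 and 0.078), and had 0.215 without WT_DCM replicate 3. The pericyte and smooth muscle list (-0.12 over 11 genes) lost it without WT_DCM replicate 3 (-0.043) or KO_DCM replicates 1 and 2 (-0.080 and -0.12), and had -0.058, -0.21 and -0.30 without WT_DCM replicates 1 and 2 and KO_DCM replicate 3. The neighbouring-tissue list (-0.24 over 9 genes, of which Acta1 fell adjusted over the list alone) lost it without WT_DCM replicate 1 (-0.40) or KO_DCM replicates 2 and 3 (-0.41 and -0.265), and had -0.42 without KO_DCM replicate 1. These 7 lists had adjusted p of 7.24e-05 to 0.0443 with the preset and 0.35 to 0.565 with an estimated correlation, and 0 of their genes passed over all genes.

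The p53 and scavenger-receptor lists had medians of -0.09 and 0.07 and did not pass camera's test (adjusted p = 0.214 and 0.402 with the preset correlation). Over all 16050 genes tested, 9 passed the threshold in KO_DCM against WT_DCM, 8 higher and 1 lower, and 1048 had an unadjusted p under 0.05 where chance gives 802. The 3 libraries of one group lay wholly above those of the other for 10.6% of genes, where chance gives 10%. The count depended on single libraries: it was 5, 0 and 3 without WT_DCM replicates 1, 2 and 3, and 22 and 45 without KO_DCM replicates 1 and 2. For the count of 0, edgeR's quasi-likelihood test gave 545 genes at an unadjusted p under 0.05. It also depended on the method: with all 8 libraries it was 87 by DESeq2, 9 by limma-voom, 7 by limma-trend on FPKM, 118 with no filter, 23 with a batch term for class and 166 with the atrial score (below) as a covariate. Among the 38 lists tested, 25 passed camera with the preset correlation (14 without KO_DCM replicate 3) and 0 passed with an estimated correlation. Without KO_DCM replicate 1, 1 list passed with an estimated correlation. An atrial cardiomyocyte score, the mean log2 CPM of 9 atrial genes around its mean over libraries, was 1.51, 0.08 and -0.67 in WT_DCM and -1.31, -2.44 and 1.66 in KO_DCM, so expression of atrial genes differed within both groups.

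The comparison of WT_DCM with WT_CONTROL asks what the disease model changed in wild-type hearts, with 1 control library. Proliferation genes were lower in WT_DCM and immediate-early genes higher. The cell-cycle list had a median log2 fold change of -1.09 over 38 genes, of which 19 fell adjusted over the list alone and 0 over all genes. The cell-cycle score was 0.74 in WT_CONTROL, -0.048, 0.06 and 0.024 in WT_DCM, and 0.078 in KO_CONTROL. The other control library thus lay near WT_DCM, and the difference rests on a high level in the lone WT_CONTROL library. Mki67, a marker of dividing cells, was at 9.90 CPM in WT_CONTROL and 3.72 ± 1 CPM in WT_DCM (SD, n = 3), a log2 fold change of -1.41 ± 0.376 (SE). Kif23, a motor protein of cytokinesis, and Ccna2, a cyclin of DNA replication and mitosis, had -1.42 ± 0.375 and -1.20 ± 0.338 (SE). The immediate-early list had a median of 0.76 over 22 genes, of which 10 rose adjusted over the list alone and 0 over all genes. Nr4a1, an orphan nuclear receptor induced by stress, was at 9.28 CPM in WT_CONTROL and 54.7 ± 19.8 CPM in WT_DCM (SD, n = 3), a log2 fold change of 2.56 ± 0.413 (SE). Fos had 1.76 ± 0.246 and Atf3, a stress-response factor, 1.49 ± 0.357 (SE). Both lists passed camera with the preset correlation (adjusted p = 6.26e-28 and 9.62e-17) and with an estimated correlation (adjusted p = 0.0224 for each). The calls with an estimated correlation were lost in both when any WT_DCM library, KO_DCM replicate 2 or KO_DCM replicate 3 was left out, and in 1 of them when KO_DCM replicate 1 was. The cardiac stress list had a median of 0.19, positive in 11 of 17 genes, of which 1 rose adjusted over the list alone and 0 over all genes. It did not pass camera (adjusted p = 0.109 with the preset and 0.775 with an estimated correlation). Its members differed in direction. Nppb, a natriuretic peptide, was at 298 CPM in WT_CONTROL and 157 ± 58.15 CPM in WT_DCM, and Acta1 at 230 and 491 ± 195 CPM (SD, n = 3).

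Matrix genes were lower in WT_DCM than in WT_CONTROL, with a median of -0.68 over 35 genes, of which 16 fell and 1 rose adjusted over the list alone and 0 passed over all genes. Sparc had a log2 fold change of -1.17 ± 0.155, Col5a1, a fibril-forming collagen, -1.11 ± 0.232, and Mmp2, a matrix-degrading protease, -0.93 ± 0.187 (SE). The matrix list had an adjusted p of 2.33e-21 with the preset and 0.343 with an estimated correlation. Fatty acid oxidation genes were higher in 32 of 32 cases, with a median of 0.40, and 0 passed over all genes or adjusted over the list alone. Acot1, a thioesterase that frees fatty acids from coenzyme A, had a log2 fold change of 1.15 ± 0.296 (SE). This list had an adjusted p of 5.62e-16 with the preset and 0.278 with an estimated correlation. The pan-macrophage list had a median of -0.53 over 18 genes and the interferon list one of -0.47 over 26, with 0 genes past the threshold over all genes or adjusted over the list alone in either. Their adjusted p were 2.73e-07 and 5.32e-05 with the preset correlation and 0.464 for each with an estimated correlation. Heat-shock and glucocorticoid-response genes had medians of 0.33 and 0.55, positive in 13 of 13 and 16 of 16 genes, with 0 past the threshold over all genes or adjusted over the list alone. Their adjusted p were 4.36e-05 and 2.61e-05 with the preset and 0.391 and 0.464 with an estimated correlation; without WT_DCM replicate 3 the glucocorticoid-response median was 0.305. Markers of blood and of other tissue differed from the lone control too. The red blood cell list had a median of -2.05, positive in 0 of 8 genes, and the B and plasma cell and mast-cell lists had -1.28 over 14 genes and -0.94 over 5, with 0 genes past the threshold over all genes or adjusted over the list alone. Their adjusted p were 1.91e-04, 3.64e-05 and 6.43e-05 with the preset and 0.464, 0.464 and 0.231 with an estimated correlation. The red blood cell score was 1.53 in WT_CONTROL and 0.62, 0.19 and -0.89 in WT_DCM. The neighbouring-tissue list had a median of 0.01 and a mean of 0.91 over 9 genes, of which 2 rose adjusted over the list alone and 0 over all genes (adjusted p = 2.61e-05 with the preset and 0.113 with an estimated correlation); its median was 0.065, 0.058 and 0.17 without WT_DCM replicates 1, 2 and 3. One of the 2 was Upk3b, a marker of mesothelium, with 17 counts in WT_CONTROL and 222, 262 and 197 in WT_DCM. Differences in matrix and macrophage genes therefore come with differences in blood and tissue markers of 1 control library. Another 8 lists passed camera with the preset correlation. Lower were the resident macrophage (-0.33), monocyte-derived macrophage (-0.52), fibroblast (-0.27) and endothelial (-0.19) lists, and higher the nuclear-encoded oxidative phosphorylation (0.12), mitochondrially encoded (0.23), muscle atrophy (0.20) and ribosomal (0.12) lists. Their adjusted p ran from 8.02e-05 to 0.024 with the preset and from 0.343 to 0.791 with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone. Without WT_DCM replicate 1 the endothelial, oxidative phosphorylation, mitochondrially encoded and ribosomal calls were lost (medians -0.14, 0.043, 0.11 and -0.009), and without WT_DCM replicate 3 that of muscle atrophy (0.14), where the fibroblast and ribosomal medians were -0.16 and 0.19.

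Over all 16050 genes, edgeR's quasi-likelihood test called 0 genes in WT_DCM against WT_CONTROL, with 871 at an unadjusted p under 0.05. DESeq2 called 44, limma-voom 0 and limma-trend on FPKM 0, while edgeR called 49 with no filter, 3 with the class term and 14 with the atrial covariate. Leaving out WT_DCM replicate 2, KO_DCM replicate 2 or KO_DCM replicate 3 gave a count of 1 each time, Nr4a1 at a log2 fold change of 2.83 in the first case and Upk3b at 4.02 in the other 2. A fit to the 4 libraries of these groups alone also gave 1, Upk3b at 4.02, and 0 lists with an estimated correlation. The WT_CONTROL library lay outside the 3 WT_DCM libraries for 49.2% of genes, where chance gives 50%. Among the 38 lists, 20 passed camera with the preset correlation and 2 with an estimated one. Msr1 had a log2 fold change of 0.98 ± 0.357 (SE) and Myc one of -0.56 ± 0.611 (SE), with adjusted p of 0.827 and 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

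The comparison of KO_DCM with KO_CONTROL asks the same of the libraries labelled KO, again with 1 control library. That control differs from the other 12 libraries in its sex genes. KO_CONTROL held 1797 counts of Xist, the RNA that silences an X chromosome in female cells, and 0 counts of Ddx3y and Eif2s3y, which lie on the Y chromosome. The other 12 libraries held at most 12 counts of Xist and at least 854 of Ddx3y. Against the floor of 3 counts in KO_CONTROL, Ddx3y was at least 311-fold and Eif2s3y at least 249-fold higher in KO_DCM. The Y-linked genes Uty and Kdm5d had 2 and 7 counts in KO_CONTROL, and were 147-fold (95% counting interval 40.4 to 1210) and 29.3-fold (14.1 to 73.1) higher in KO_DCM. The comparison therefore sets libraries with Y-linked counts against 1 without.

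Apart from sex genes, interferon-induced genes rose in KO_DCM against KO_CONTROL. Gbp6 was at 29.9 CPM in KO_CONTROL and 89.9 ± 3.51 CPM in KO_DCM (SD, n = 3). Its log2 fold change was 1.59 ± 0.166 (SE), with an adjusted p of 0.0112 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same test Lrrc4b, a synaptic adhesion protein, had 1.58 ± 0.203 (SE, adjusted p = 0.0426), and Gm43302, named after its values were seen, 1.60 ± 0.17 (SE, adjusted p = 0.0115). The calls of Gbp6 and Gm43302 were lost without WT_DCM replicate 2 (1.59 and 1.60). That of Lrrc4b was lost without any 1 of the WT_DCM libraries (1.57 to 1.58) or without KO_DCM replicate 1 (1.54). The interferon list had a median of 1.53, positive in 26 of 26 genes, of which 22 rose adjusted over the list alone and 1 over all genes. Its adjusted p was 3.39e-40 with the preset and 0.117 with an estimated correlation. Other immune lists had positive medians too: pan-macrophage 0.39 (positive in 18 of 18 genes), class II antigen presentation 0.67 (10 of 10), inflammatory cytokines 0.79 (13 of 16) and neutrophil 1.40 (5 of 6), with 0 genes past the threshold over all genes or adjusted over the list alone. Their adjusted p were 4.74e-04, 0.00548, 0.0036 and 0.00721 with the preset and 0.694, 0.577, 0.543 and 0.577 with an estimated correlation. Without KO_DCM replicate 3 the pan-macrophage and neutrophil calls were lost, at medians of 0.15 and 0.60.

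Adipocyte genes were lower in KO_DCM than in KO_CONTROL, with a median of -2.62 over 12 genes, of which 9 fell and 1 rose adjusted over the list alone and 0 passed over all genes. The list had an adjusted p of 2.16e-15 with the preset and 0.117 with an estimated correlation. The adipocyte score was 1.04 in KO_CONTROL and -0.78, -0.86 and -0.19 in KO_DCM, and the atrial score of KO_CONTROL was 1.06. The fibroblast list had a median of -0.61 over 14 genes, of which 5 fell adjusted over the list alone and 0 over all genes (adjusted p = 1.98e-08 with the preset and 0.312 with an estimated correlation). Mast-cell genes had a median of -1.78 over 5 genes, of which 4 fell adjusted over the list alone and 0 over all genes (adjusted p = 1.85e-06 with the preset and 0.134 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had a median of -0.29 over 52 genes, with 0 past the threshold over all genes or adjusted over the list alone (adjusted p = 4.6e-08 with the preset and 0.694 with an estimated correlation). The cell-cycle and matrix lists had medians of -0.45 and -0.32, with 0 and 1 genes that fell adjusted over the list alone and 0 over all genes in either. Their adjusted p were 2.6e-06 and 7.49e-06 with the preset and 0.143 and 0.694 with an estimated correlation. Without KO_DCM replicate 2 the cell-cycle median was -0.735, and the matrix median was -0.19 and -0.55 without KO_DCM replicates 1 and 3. Lower too were the atrial (-0.45), heat-shock (-0.47), neighbouring-tissue (-0.35) and ribosomal (-0.19) lists, with 0, 1, 1 and 0 genes that fell adjusted over the list alone and 0 over all genes. Their adjusted p were 0.0218, 5.1e-05, 0.0208 and 0.0048 with the preset and 0.751, 0.394, 0.312 and 0.779 with an estimated correlation. The atrial call was lost without KO_DCM replicate 1 (-0.17) or KO_DCM replicate 2 (-0.12), with a median of -4.09 without KO_DCM replicate 3. The neighbouring-tissue call was lost without KO_DCM replicate 3 (-0.52), and the ribosomal one without KO_DCM replicate 2 (-0.019), with -0.31 without KO_DCM replicate 3.

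In all, 9 genes passed in KO_DCM against KO_CONTROL, 8 higher and 1 lower, of which 4 were not sex genes, and 1238 had an unadjusted p under 0.05. Leaving out WT_DCM replicate 2 gave 5, KO_DCM replicate 2 gave 18 and KO_DCM replicate 3 gave 26. DESeq2 gave 96, limma-voom 6 and limma-trend on FPKM 3, and edgeR gave 102 with no filter, 23 with the class term and 39 with the atrial covariate. A fit to the 4 libraries of these groups alone gave 5, all of them sex genes, and ended the calls of Gbp6, Lrrc4b and Gm43302 at log2 fold changes of 1.59, 1.58 and 1.59. Among the 38 lists 16 passed with the preset correlation, and with an estimated one only the list of sex genes did (adjusted p = 0.0184). That call was lost when WT_DCM replicate 2 or any 1 KO_DCM library was left out, with a count of 0 lists each time, and in the fit to these 4 libraries. Msr1 and Myc had log2 fold changes of -0.12 ± 0.332 and -0.26 ± 0.594 (SE), with adjusted p of 0.934 and 0.918 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without KO_DCM replicate 2 both turned in sign, to 0.04 and 0.13.

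The interaction of label and disease asks whether the difference from control itself differed between KO and WT, and rests on 2 lone control libraries. By edgeR's quasi-likelihood test it called 4 genes, the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d, which follow the sex genes of KO_CONTROL. DESeq2 called 37, among them these 4, limma-voom 1 and limma-trend on FPKM 3, and edgeR called 44 with no filter, 8 with the class term and 7 with the atrial covariate. By edgeR's quasi-likelihood test 811 genes had an unadjusted p under 0.05, where chance gives 802. The count was 7 without KO_DCM replicate 1. The interferon list had an interaction median of 1.98, positive in 26 of 26 genes, of which 23 rose adjusted over the list alone and 0 over all genes. Its adjusted p was 4.11e-47 with the preset and 0.0667 with an estimated correlation. The interferon score was -0.009 in WT_CONTROL and -0.751 in KO_CONTROL. Part of the interaction median thus comes from the 2 lone controls, beyond the median of 1.15 between KO_DCM and WT_DCM. Of the 38 lists, 19 passed with the preset correlation, and the list of sex genes alone passed with an estimated one (adjusted p = 0.00447). Without KO_DCM replicate 1, 2 lists passed with an estimated correlation. Msr1 had an interaction log2 fold change of -1.1 ± 0.482 (SE) and Myc one of 0.30 ± 0.862 (SE), with adjusted p of 0.916 and 0.967 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without KO_DCM replicate 3, that of Myc turned to -0.36.

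KO_CONTROL and WT_CONTROL, with 1 library each, differ in sex genes as well as in label, and their difference has no replicate check. Xist, which female cells express, had 1797 counts in KO_CONTROL and 1 in WT_CONTROL, while the Y-linked Ddx3y had 0 and 964. Msr1 had 83 and 53 counts, and Myc 90 and 74. Of 13815 genes, 507 differed at least 2-fold, 191 higher and 316 lower in KO_CONTROL. Scaled by total counts, KO_CONTROL vs WT_CONTROL split into 118 higher and 480 lower genes. With a prior of 2 CPM 204 genes differed at least 2-fold, and with a floor of 5 CPM 288.

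The first experiment follows wild-type hearts over 4 weeks of doxorubicin injections, with 1 library per week and no test. Matrix and fibroblast genes were lower in each later library than at week 0. Postn was at 126 CPM at week 0 and at 15.3, 29.1, 27.9 and 36.2 CPM at weeks 1 to 4. Eln, the elastic fibre protein, was at 172 CPM and then at 37.6, 46.9, 46.3 and 51.2 CPM. The matrix list had medians of -1.54, -1.01, -0.82 and -1.14 over 34 genes at weeks 1 to 4, each at percentile 0 of 10000 random lists matched on size and expression. The random genes were drawn independently, so lists of co-expressed genes can reach such extremes together, and a percentile does not test its list. The fibroblast list had medians of -0.75, -0.60, -0.82 and -0.64 over 14 genes, also at percentile 0. Other lists of cells that are not cardiomyocytes were lower too: the endothelial list had medians of -0.555, -0.40, -0.38 and -0.27 over 17 genes at weeks 1 to 4, and the pericyte and smooth muscle list -0.55, -0.51, -0.61 and -0.47 over 10, at percentiles of 0.01 or below. Atrial and fat genes, markers of other tissue in the sample, moved with them. The atrial list had medians of -2.47, -3.36, -3.01 and -2.60, and the adipocyte list of -3.58, -3.76, -3.61 and -3.25. With genes at 0 counts set at their bound, these became -2.47, -3.08, -3.01 and -2.60 and -3.52, -3.76, -3.61 and -3.25.

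Macrophage genes were lower at weeks 1 to 4 as well. The pan-macrophage list had medians of -1.11, -0.90, -0.96 and -0.70 over 18 genes, and the resident (reparative) macrophage list of -0.88, -0.85, -0.91 and -0.72 over 20 genes. All 8 values lay at percentile 0 of the random lists. Msr1 counts were 110 at week 0 and 37, 37, 24 and 32 at weeks 1 to 4, a week 4 ratio of 0.319 (95% counting interval 0.208 to 0.476). Cx3cr1, a chemokine receptor of monocytes and macrophages, was at 9.12 CPM at week 0 and 3.51, 2.52, 1.1 and 3.97 CPM later. Igf1, a growth factor made by resident macrophages among other cells, was at 30.8 CPM and then 10.9, 15.1, 13.6 and 15.6 CPM. Myc counts were 43 at week 0 and 46, 18, 62 and 39 later, with a week 4 ratio of 0.993 (0.627 to 1.57). The c-Myc target list had medians of 0.20, 0.17, 0.18 and 0.11 over 30 genes, at percentiles 99.3, 99.1, 99.5 and 92.2, and its week 4 value was -0.07 with total-count scaling, where the median of all genes was -0.19. The interferon list had medians of -0.26, -0.27, -0.25 and -0.24 over 24 genes, at percentiles 1.28, 0.67, 1.54 and 2.24.

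Stress genes of the cardiomyocyte were higher in the later libraries. Nppb, the B-type natriuretic peptide released by strained ventricles, was at 37 CPM at week 0 and 186, 191, 128 and 158 CPM at weeks 1 to 4, a week 4 ratio of 4.27 (95% counting interval 3.9 to 4.68). Myh7 was at 67.6 CPM and then 4051, 339, 303 and 196 CPM. Nppa, the atrial natriuretic peptide, went the other way with the atrial genes, from 97.1 CPM to 15.7 CPM at week 4. The cardiac stress list had medians of 0.56, 0.35, 0.47 and 0.52 over 16 genes, at percentiles of 99.9 or above. Cdkn1a, a p53 target that halts the cell cycle, was at 33.5 CPM at week 0 and 74.8, 46.7, 106 and 75.7 CPM later, while the p53 list had medians between -0.16 and -0.05. The heat-shock list had medians of 0.44, 0.67, 1.01 and 0.60 over 13 genes. Hspa1b stood apart at week 3, with 1670 counts against 39 at week 0, a ratio of 50.2 (36.5 to 70.8). Sarcomere genes, which mark heart muscle in general, had medians of 0.32, 0.40, 0.36 and 0.19.

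Among 13323 genes, 935, 737, 950 and 642 differed at least 2-fold from week 0 at weeks 1, 2, 3 and 4, with 188, 151, 242 and 105 of them higher. With a prior of 2 CPM these counts were 398 (time course, week 1 vs week 0), 302, 404 and 235, and with a floor of 5 CPM 498, 381, 499 and 300. The 4 comparisons share the week 0 library, so a feature of that library appears in each. Principal component 1, with 51.2% of the variance, set week 0 at -45.5 and the later weeks between -0.6 and 17.4. Scaling by total counts moved the median log2 fold change of all genes to -0.12, -0.14, -0.14 and -0.19, so directions are given relative to that shift.

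**Figure D2:**
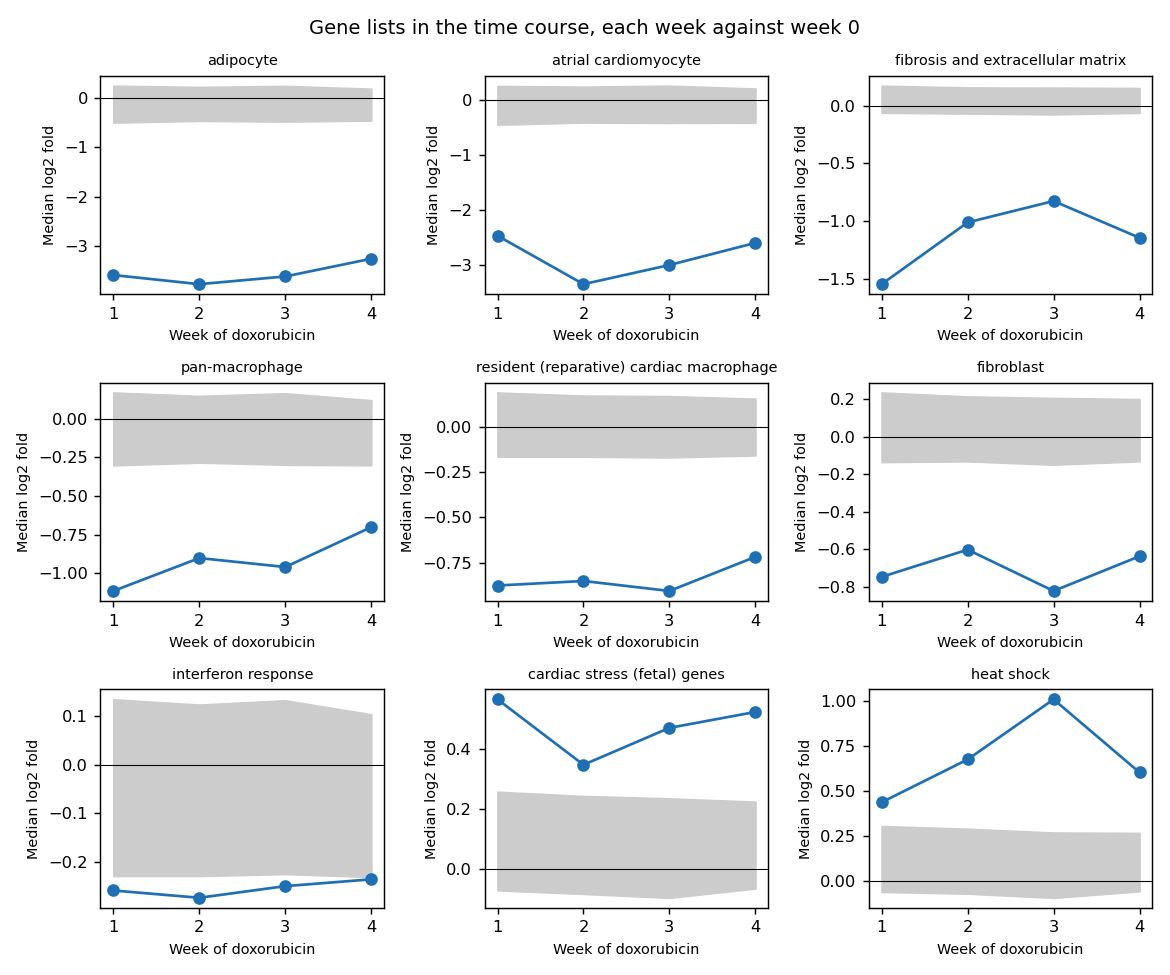
Median log2 fold change against week 0 (y axis) of 9 gene lists at weeks 1 to 4 (x axis), with 1 library of 5 mixed hearts per week; grey bands show the central 95% of 10000 random lists matched on size and expression. The matrix, fibroblast, macrophage, atrial and adipocyte lists lie below the band at each week, and the cardiac stress and heat-shock lists above it.

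The fold changes of the wild-type disease model were set beside those of the time course, across 12885 genes measured in both experiments. Spearman's correlation of WT_DCM against WT_CONTROL with weeks 1, 2, 3 and 4 against week 0 was 0.376, 0.235, 0.266 and 0.334, and Pearson's was 0.313, 0.17, 0.211 and 0.236. Genes are not independent replicates, and the experiments share no library. The matrix list was lower in both, with medians of -0.68 in WT_DCM against WT_CONTROL and -1.54, -1.01, -0.82 and -1.14 at weeks 1 to 4. So was the pan-macrophage list, at -0.53 and then -1.11, -0.90, -0.96 and -0.70. The cell-cycle list, at -1.09 in WT_DCM against WT_CONTROL, had medians of -0.88, 0.05, -0.10 and -0.22 at weeks 1 to 4. Other changes differed in direction. The atrial list had 0.42 in WT_DCM against WT_CONTROL and -2.47, -3.36, -3.01 and -2.60 at weeks 1 to 4. The immediate-early list had 0.76 and then -0.07, -0.24, 0.37 and -0.16. Nppb was at 298 CPM in WT_CONTROL and 157 CPM in WT_DCM, against a week 4 ratio of 4.27. Msr1 was at 1.94 and 3.85 CPM, against a week 4 ratio of 0.319.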

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

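The results in this part are those where the interaction test gave a difference between KO and WT in the change from control. The counts of splits were planned, while the tests of gene-length class and of macrophage content were chosen only after the result was seen.

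By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 genes passed the interaction, with fitted log2 fold changes of 12.75 for Ddx3y, 12.74 for Eif2s3y, 7.04 for Uty and 4.84 for Kdm5d. The first 2 depend on the prior count and are no bound, because KO_CONTROL held 0 counts of each. The list of sex genes had an interaction median of 7.04 (camera adjusted p = 1.3e-81 with the preset and 0.00447 with an estimated correlation). These values follow from 1797 counts of Xist and absent or near-absent Y-linked counts in KO_CONTROL, while KO_DCM and both WT groups carry Y-linked counts. A female animal or a library from another source would give such counts; no test tells these apart, and the labels give no sex.

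With the preset correlation 18 further lists passed the interaction, and 0 of these 18 with an estimated correlation. The immune lists among them were interferon response (median 1.98), pan-macrophage (0.78), monocyte-derived macrophage (0.99), inflammatory cytokines (0.89) and B and plasma cell (1.80), with estimated-correlation adjusted p of 0.0667, 0.505, 0.287, 0.624 and 0.608. Those of tissue structure and growth were cell cycle (0.37), matrix (0.36), fibroblast (-0.32), atrial (-0.83), adipocyte (-2.23) and neighbouring tissue (-0.97), at 0.505, 0.741, 0.624, 0.624, 0.172 and 0.0658. Those of metabolism were fatty acid oxidation (-0.35), nuclear-encoded oxidative phosphorylation (-0.40), mitochondrially encoded (-0.36) and ribosomal proteins (-0.32), at 0.608, 0.624, 0.624 and 0.73. Those of acute response were heat shock (-0.66), glucocorticoid response (-0.54) and immediate-early (-0.59), at 0.19, 0.624 and 0.0658. Of these calls, WT_DCM replicate 1 left out ended atrial (-0.10), fibroblast (-0.30) and mitochondrially encoded (-0.21), WT_DCM replicate 2 cytokines (0.88) and fibroblast (-0.25), and WT_DCM replicate 3 cytokines (0.60) and matrix (0.23). KO_DCM replicate 1 left out ended cytokines (1.02), atrial (-0.48) and fibroblast (-0.25), KO_DCM replicate 2 cell cycle (0.29), atrial (-0.49) and fibroblast (-0.26), and KO_DCM replicate 3 cytokines (0.77), cell cycle (0.36), matrix (0.26) and mitochondrially encoded (-0.32). Other medians moved over 1.5-fold with their calls kept: atrial (-1.32 without WT_DCM replicate 3, -4.5 without KO_DCM replicate 3), B and plasma cell (0.97 without KO_DCM replicate 1), monocyte-derived macrophage (1.58 and 0.63 without WT_DCM replicates 1 and 3), glucocorticoid response (-0.34 without WT_DCM replicate 3, -0.34 and -1.05 without KO_DCM replicates 2 and 3) and ribosomal proteins (-0.19 without WT_DCM replicate 1, -0.17 without KO_DCM replicate 2). All 19 medians rest on 1 control library per label, which differ in sex genes. The controls also differ in interferon score, at -0.009 in WT_CONTROL and -0.751 in KO_CONTROL.

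The pattern weighed here is the higher expression of interferon-induced genes in the libraries labelled KO_DCM than in those labelled WT_DCM. The test of the gene-length class argues against that class as the whole cause: with the class as a batch term, which raised the count of genes from 9 to 23, the interferon median was 1.22 and the list kept its call with the preset correlation. More macrophages in the KO_DCM hearts remain open, since the interferon score minus the pan-macrophage score was higher in KO_DCM by 0.615 ± 0.35 (SE, n = 3 each), less than 2 SE from 0. Whether pan-macrophage genes respond to interferon themselves was not tested. If some do, the subtraction removes part of the interferon difference, so it cannot settle macrophage content. The real split of the 6 DCM libraries gave an interferon median of 1.15 and the highest other split 1.00 in size (1 of 10 splits as far from 0), and 10 splits are too few for a share under 0.05. An effect of SR-A1 on interferon signalling may be one cause, but litter, housing, infection or a batch shared by the KO_DCM mice is confounded with the label and cannot be told apart from it.

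The real split called 9 genes and the highest other split 1602, so 2 of 10 splits gave as many genes. That other split sets WT_DCM replicate 1, KO_DCM replicate 1 and KO_DCM replicate 3 against the rest, which is the gene-length class, and it points to a structure of the libraries other than their groups. For lists with the preset correlation the real split gave 25 and the others 8 to 21, so 1 of 10 splits gave as many. Many preset list calls therefore arise without a split by label. With 10 splits no share can be under 0.05.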

How the results depend on the processing

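The gene-length class term, the atrial covariate, the removal of mitochondrial genes and of KO_CONTROL, the fits to 4 libraries and the alternatives for the 2 control libraries were chosen after seeing the data; the others were planned. Among the main results 129 of 180 alternative values stayed within their limits, 25 rose past them, 18 fell short and 8 moved. For named genes of the second experiment these were 1350 of 1481, with 79 gaining a call, 43 losing one and 9 turning in sign. For list calls 1036 of 1149 stayed, 109 were lost and 4 turned in direction. In the time course 245 of 304 list medians and 167 of 244 gene values stayed, 58 and 77 moved, and 1 and 0 turned, where a turn of sign was counted only for medians outside the central 95% of random lists.

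With no filter, genes past the threshold numbered 118 for KO_DCM against WT_DCM, 49 for WT_DCM against WT_CONTROL, 102 for KO_DCM against KO_CONTROL and 44 for the interaction, where the filtered test gave 9, 0, 9 and 4. DESeq2 gave 87, 44, 96 and 37, the class term 23, 3, 23 and 8, and the atrial covariate 166, 14, 39 and 7. All 9 genes of KO_DCM against WT_DCM were among the calls of each of these 4 alternatives. Limma-trend gave 3 for KO_DCM against KO_CONTROL, and limma-voom 1 for the interaction. For KO_DCM against WT_DCM, RLE and upper-quartile scaling kept all 9 genes, robust estimation kept 8, and limma-trend called 7, of which 5 were among the 9. Of the calls with no filter, 0 were genes that the filter had left out in each comparison, so the added calls were genes already tested. Beyond this, the cause was not tested for any of these shifts.

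Leaving out 1 DCM library at a time gave 0 to 45 genes for KO_DCM against WT_DCM (0 without WT_DCM replicate 2, 45 without KO_DCM replicate 2), 0 to 1 for WT_DCM against WT_CONTROL, 5 to 26 for KO_DCM against KO_CONTROL and 4 to 7 for the interaction. At the count of 0 in KO_DCM against WT_DCM, edgeR's quasi-likelihood test had 545 genes at an unadjusted p under 0.05. Lists of KO_DCM against WT_DCM ran from 14 (without KO_DCM replicate 3) to 24.

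Signs turned for Msr1 in KO_DCM against WT_DCM (from -0.05 to 0.093 with the atrial covariate, and from -0.24 to 0.11 when 1 library was left out) and in KO_DCM against KO_CONTROL (from -0.12 to 0.14 with the atrial covariate, and -0.31 to 0.037). For Myc in KO_DCM against KO_CONTROL they turned from -0.26 to 0.23 with the atrial covariate (and -0.92 to 0.13), and in the interaction from 0.30 to between -0.36 and 0.69. The ribosomal median turned to -0.023 with the class term in WT_DCM against WT_CONTROL and to 0.038 with the atrial covariate in KO_DCM against KO_CONTROL. In KO_DCM against WT_DCM the direction of camera's test, but not the median's sign, turned for the B and plasma cell list without KO_DCM replicate 1 (median 0.095, with leave-outs up to 0.68) and for the glucocorticoid-response list without KO_DCM replicate 3 (0.022, up to 0.48). The oxidative phosphorylation median at week 1 was -0.062 with total-count scaling, which moved the median of all genes to -0.121, so it stayed above that median. The cause was not tested for the other turns.

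With a prior of 2 CPM the genes changed 2-fold numbered 398 (time course, week 1 vs week 0), 302, 404 and 235 at weeks 1 to 4, and with a floor of 5 CPM 498, 381, 499 and 300. KO_CONTROL against WT_CONTROL gave 204 and 288. A higher floor leaves out genes of low counts by construction; a higher prior leaves out none but shrinks their fold changes. Spearman's correlation with the first experiment was 0.42, 0.271, 0.288 and 0.409 with a floor of 5 CPM. Pearson's, without that floor, was 0.313, 0.17, 0.211 and 0.236.

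A replicate block for the 6 DCM libraries gave 11 genes, of which 8 were among the 9. Correlations of same-numbered libraries were 0.196, 0.298 and -0.307, so the numbers are not taken to pair them. The block was not run for the other comparisons, whose controls have 1 library. Fits to the 4 libraries of the compared groups alone gave 1 gene for WT_DCM against WT_CONTROL and 5 for KO_DCM against KO_CONTROL, all 5 among its 9. A pseudocount of 0.1 applied only to files with FPKM alone and was not run, and robust estimation and the 2-fold threshold do not enter the list test.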

Other observations

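The tests of tissue content and of clock genes in this part were chosen only after the result was seen.

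Clock genes differed between week 0 and the later libraries of the time course. Arntl, the transcription factor BMAL1 that drives the clock, was at 2.37 CPM at week 0 and 14.6, 14.4, 24.4 and 22.4 CPM at weeks 1 to 4, a week 4 ratio of 9.42 (95% counting interval 6.72 to 13.6). Dbp, a clock output gene of opposite phase, was at 78.1 CPM and then 15.8, 8.2, 9.36 and 4.79 CPM, a week 4 ratio of 0.0613 (0.0475 to 0.078). The inducible chaperones Hspa1a and Hspa1b, whose reads are not fully told apart, were at 40.3 and 122 CPM in the week 3 library and at 0.999 and 2.43 CPM at week 0. Nr4a3, an immediate-early nuclear receptor, stood at 68.8 CPM at week 3 and 1.5 CPM at week 0. The immediate-early list had a median of 0.37 at week 3, at percentile 100 of the random lists. At week 4 the fatty acid oxidation list had a median of 0.39 at percentile 100. Pdk4, which spares glucose when fat is burned, was at 1205 CPM there against 436 CPM at week 0 and 420, 411 and 499 CPM between. The haemoglobin gene Hbb-bs was at 80.3 CPM at week 0 and 1.85, 25.8, 21.9 and 21.1 CPM later, and the red blood cell list had medians of -2.41, -1.50, -1.46 and -1.59, or -2.18 at week 1 with genes at 0 counts set at their bound.

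Matrix, fibroblast and macrophage genes were lower at weeks 1 to 4 than at week 0, and so were endothelial genes, pericyte and smooth muscle genes and markers of other tissue. Myl7, an atrial myosin light chain, was at 340 CPM at week 0 and 1.28, 0.21, 0.22 and 8.68 CPM later, and Cfd, an adipocyte protein, at 27 CPM and then 0, 0.28, 0.293 and 1.09 CPM. The highest of the 8 medians of the atrial and adipocyte lists was -2.47, while the sarcomere medians were at most 0.40, which is consistent with more atrial tissue and fat in the week 0 hearts. Lower matrix expression after doxorubicin at a given atrial content also stays open: in the second experiment the matrix median in WT_DCM against WT_CONTROL was -0.71 with the atrial score as a covariate. The atrial list shares Nppa with the cardiac stress list, the adipocyte list shares 0 genes with others, and the 2 explanations may act together in the time course.

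The clock genes may reflect hearts taken at another time of day. The median of Arntl, Npas2, Clock and Nfil3 was above 0 and that of 9 genes of opposite phase below 0 in 4 of 4 weeks, at 1.24, 1.64, 1.82 and 1.88 against -0.82, -0.80, -1.36 and -1.39. A shift of the clock by doxorubicin remains open, because in the second experiment the same difference was -0.42 ± 1.69 (SE) between WT_DCM and WT_CONTROL. That SE pools the spread of both DCM groups. The first median minus the second was -0.542, 0.839 and -0.868 in WT_DCM, and -2.396, 1.072 and -1.821 in KO_DCM, which spread wider. The 4 weeks share the week 0 library, so a feature of that library alone would give the same signs. The labels give no time of collection.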
